A study of Mus musculus with 12 samples.

How the data were processed

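RNA was sequenced from the aortas of 12 male C57BL/6J mice in 3 groups of 4, each library taken from a separate animal per the labels' protocols. Total RNA was extracted with TRIzol, purified on columns and made into libraries with an Illumina TruSeq v2 kit, per the labels' protocols, and that kit does not record which strand a transcript came from. Reads of genes that overlap on opposite strands could therefore not be told apart. The submitters' processing notes name bcl2fastq, DESeq2 and the mouse build mm10, without versions. The aligner, the counting tool and the annotation release are not given in the sources used here.

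The authors deposited 1 table of raw counts per RefSeq accession and library, and 2 tables of their own comparisons, PPE week 1 and PPE week 2 each against the control group, with a log2 fold change, a p-value and an adjusted p-value per accession. The count table held 34755 accessions, of which 14322 had a count of 0 in all 12 libraries. RefSeq's gene table for GRCm38.p6, the assembly behind mm10, named 34424 of the accessions and GENCODE's table a further 192, which left 139 without a symbol. The total count per library lay between 8343313 and 12269131. Accession NR_046233, which RefSeq describes as a precursor of ribosomal RNA, took 19.5 to 49.9% of it, so that 4835305 to 9169690 counts per library were left for all other features. Among counts of 2 to 20, between 66.0 and 75.6% per library were even, an excess that counting each read of a pair separately would give, and halved counts were therefore among the alternatives. No pair of libraries of a group agreed within sampling noise, since the chi-square per feature between replicates was 15.6 to 97.6, and each library counted as 1 sample.

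The deposited counts appear to leave out reads shared between isoforms of a gene. Of 655 accessions without bases of their own, 96.5% had a count of 0, against 11.0% of 2544 accessions with at least 100 bases of their own, among genes with at least 100 counts. Genes with several overlapping accessions are therefore undercounted: over all 12 libraries Gapdh had 2 counts, Timp1 0, Thbs1 4, Il6 29 and Spp1 50, and none of these 5 could be tested. The level of Myh11, Tpm1 and Dmd in CPM (counts per 1000000 counts of a library) is likewise that of the part unique to 1 accession. A gene with near-identical copies, such as Ly6c2, H2-Q5, the Ifit genes, Hspa1a and Hspa1b, is uncertain.

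From the counts, differential expression was computed with edgeR 4.0.16 in R 4.3.3. Accessions were kept by filterByExpr with its default settings, which left 12756 accessions of 12273 genes. Libraries were scaled by TMM, and a quasi-likelihood model with robust estimation of the spread was fitted to all 12 libraries with 1 mean per group, so that the 3 groups shared 1 estimate of the spread. The biological coefficient of variation was 0.512. The comparisons were PPE week 1 against saline, PPE week 2 against saline and PPE week 2 against PPE week 1, each two-sided, with Benjamini-Hochberg adjustment over all accessions and an adjusted p under 0.05 as the threshold. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Group levels are given as mean ± SD of TMM-scaled CPM over 4 libraries. Where a gene had several tested accessions, the 1 with the highest mean CPM stood for it. Differences of single values between groups were tested by two-sided exact permutation, for which 4 libraries against 4 allow no p below 0.0286.

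A total of 38 gene lists with 615 symbols, 481 of them tested, covered the cell types of the aorta and of the tissue around it, the extracellular matrix, inflammation and metabolism. They were tested with camera from limma 3.58.1 on voom log2 CPM with a preset correlation of 0.01 between genes, adjusted over the 38 lists, again with a correlation estimated from the data, and with fry, which asks whether a list's genes move on balance in 1 direction. No list kept its camera call with an estimated correlation in any of the 3 comparisons, while 4, 3 and 6 of the 38 lists, in the order of the comparisons, then had an unadjusted p under 0.05. Fry did not pass every list that camera called. At PPE week 1 its adjusted p was 0.0650 for T and NK cell and for cell cycle, and 0.104 for dendritic cell. For brown adipocyte it was 0.205 and for fatty acid oxidation 0.486. The other lists called there had 0.0127 to 0.0496. At PPE week 2 against saline it was 0.364 for basement membrane and for Schwann cell and neuron, and 0.0502 for activated fibroblast. A list's score in a library is the median over its tested genes of log2 CPM, computed with a prior count of 2, after subtracting each gene's mean over the 12 libraries. Where the closing section names a mean score, the mean over genes takes the place of that median. Counts of called members are given over all genes tested and adjusted over the list alone.

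Named genes were taken by a fixed rule: the 10 largest changes in each direction among called genes with at least 5 CPM on average and no overlap between the libraries of the 2 groups, without predicted genes and gene segments; the 3 members of each list with the smallest p; and 22 genes of matrix, contraction and inflammation, called or not. Genes named outside the rule, as further members of a list, were chosen after their values were seen. Groups, comparisons, the test, the gene lists, the rule for named genes and the main alternatives were chosen before the data were examined. Those alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, scaling by median of ratios, by the upper quartile and by library size only, 2 other filters on low counts, a fit of only the 8 libraries compared, the replicate number as a block, estimation that is not robust, each library left out in turn, an adjusted p under 0.01, a test against a fold of 1.5 (glmTreat) and the estimated correlation for lists. A further 5 were added after the data were seen: NR_046233, Lars2 and Mir6236 left out, counts summed per gene, counts halved, saline replicate 2 and PPE week 2 replicate 1 both left out, and the log2 share of NR_046233 as a covariate.

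The test was first tried on simulated counts with the means and library sizes of these data, 12756 features of which 200 were changed. In the simulated comparison of PPE week 1 with saline it found 0% of 67 genes changed by a fold of 1.5, 13.4% of 67 changed by a fold of 2 and 47.0% of 66 changed by a fold of 4, and 2.44% of its calls were unchanged genes. DESeq2 found 4.48%, 23.9% and 56.1% of the same genes, with 16.4% of its calls being unchanged genes. In the simulated comparison of PPE week 2 with saline edgeR found 1.49%, 16.4% and 51.5%, with 2.13% of its calls unchanged, and in that of PPE week 2 with PPE week 1 it found 0%, 11.9% and 59.1%, with 6% of its calls unchanged. With 4 libraries per group a gene that did not pass the test can therefore still differ by a fold of 2 or more. A count of 0 in a library allows a level of up to 0.216 to 0.447 TMM-scaled CPM, depending on the library, from 3 counts. This covers counting error only.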

Results

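RNA was measured in the aortas of 12 male mice, 4 in each of 3 groups. The saline group had its infrarenal aorta infused with saline and was harvested at day 7. The others were infused with porcine pancreatic elastase (PPE), an enzyme that digests elastic fibres and is used to make the aorta dilate. They were harvested at day 7 (PPE week 1) or day 14 (PPE week 2). The total count per library was 8343313 to 12269131 and did not pass a test between any pair of groups. The two-sided exact permutation p was 0.543 for PPE week 1 against saline, 0.943 for PPE week 2 against saline and 0.429 between the PPE weeks (n = 4 per group). NR_046233, the precursor of ribosomal RNA, took 41.3% ± 6.48 of the counts in saline, 30.4% ± 6.34 at PPE week 1 and 20.4% ± 1.13 at PPE week 2 (SD, n = 4). Against saline the share was lower at both PPE weeks (two-sided exact permutation p = 0.0286 each, the smallest that n = 4 per group allows), and between the PPE weeks the exact p was 0.0571. The share per library was 36.4, 49.9, 42.9 and 36.2% in saline replicates 1 to 4, 34.6, 31.9, 21.0 and 34.0% at PPE week 1, and 22.1, 19.5, 20.1 and 20.1% at PPE week 2. Log2 CPM of the 12756 tested features correlated with a mean Pearson r of 0.888 between saline libraries, 0.935 between PPE week 1 libraries and 0.854 between PPE week 2 libraries, across genes, which are not independent replicates.

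The comparison of PPE week 1 with saline asks what differs in the aorta 7 days after elastase, at the same day as the control. Genes of the contractile apparatus of smooth muscle were lower. Acta2, smooth muscle actin, was at 1497 ± 403 CPM against 3569 ± 512 in saline (mean ± SD, n = 4 each), 2.38-fold lower (log2 fold change -1.25 ± 0.25 SE, adjusted p = 0.0116). Its accession is NM_007392, at chromosome 19, 34240336 to 34255585 (mm10). Itga8, an integrin subunit of smooth muscle, was 6.40-fold lower, at 213 ± 94.1 against 1365 ± 186 CPM (-2.68 ± 0.32, adjusted p = 0.00144; NM_001001309, chromosome 2, 12106632 to 12301985). Cnn1, the actin-binding calponin, was 3.60-fold lower (-1.85 ± 0.30), and Myh11, smooth muscle myosin heavy chain, 5.54-fold lower (-2.47 ± 0.51). Of 19 tested genes in the smooth muscle contractile list, 13 fell and none rose, 15 when adjusted over the list alone. Their median was -1.25 (camera adjusted p = 2.84e-16; adjusted p = 0.314 with an estimated correlation; fry adjusted p = 0.0137). Genes of smooth muscle ion channels and signalling fell in 8 of 15 cases and rose in 1, the same when adjusted over the list alone. The median was -0.98 (camera adjusted p = 6.48e-07; adjusted p = 0.314 with an estimated correlation). Among them was Rgs5, a regulator of G-protein signalling in vascular mural cells, at 735 ± 212 against 3531 ± 577 CPM (-2.26 ± 0.30, adjusted p = 0.00211; NM_009063, chromosome 1, 169655501 to 169695813). The gene that rose was Agtr1a, the angiotensin II receptor, at 6.38 ± 2.71 against 1.73 ± 0.313 CPM (1.87 ± 0.52, adjusted p = 0.0348). Its adjusted p was 0.0598 to 0.112 without any of saline replicates 1 to 4 or PPE week 1 replicates 2, 3 and 4, and limma-voom, the fit without a low-count filter and the replicate block did not call it. Dmd, dystrophin of the muscle cell membrane, was 6.94-fold lower (-2.79 ± 0.36, adjusted p = 0.00202; NM_007868, chromosome X, 82814664 to 85205050). Adventitial fibroblast genes fell in 6 of 15 cases, 9 when adjusted over the list alone. For these genes the median was -0.71 (camera adjusted p = 2.53e-06; adjusted p = 0.293 with an estimated correlation). Among them was the matrix proteoglycan Ogn, at 107 ± 26.1 against 288 ± 25.04 CPM (-1.43 ± 0.23, adjusted p = 0.00328). None of 17 endothelial genes was called by edgeR, with 1 higher and 1 lower at an unadjusted p under 0.05 and 1 called higher by each of DESeq2 and limma-voom. Their median was 0.02 (camera adjusted p = 0.958). The share of NR_046233 was lower in the same PPE libraries. With that share as a covariate, an alternative added after the data were seen, 3 of the 19 contractile genes were called. The calls of Acta2, Cnn1 and Myh11 ended (-1.31, -1.69 and -2.24). The list's median was then -1.28, with a median standard error of 0.416 against 0.305 without the covariate.

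Genes of several types of immune cell were higher at PPE week 1. Cd68, a lysosomal protein of macrophages, was at 119.7 ± 16.6 CPM against 42.8 ± 4.90 in saline (n = 4 each), 2.79-fold higher (1.48 ± 0.23, adjusted p = 0.00156; NM_001291058, chromosome 11, 69664213 to 69666170). Cxcl10, a chemokine that interferon induces, was 11.3-fold higher, at 120.0 ± 38.1 against 10.5 ± 5.89 CPM (3.50 ± 0.64, adjusted p = 0.00982; NM_021274, chromosome 5, 92346638 to 92348889). Ncr1, a receptor of natural killer cells, was 6.63-fold higher (2.73 ± 0.56), and Hdc, which makes histamine, 13.5-fold higher (3.76 ± 0.68), a call that limma-voom did not make. With the share of NR_046233 as a covariate the calls of Cxcl10, Ncr1 and Hdc ended (3.36, 2.62 and 4.16). Of 16 macrophage and monocyte genes 5 rose, 13 when adjusted over the list alone with 1 lower. Their median was 1.26 (camera adjusted p = 1.12e-07; adjusted p = 0.314 with an estimated correlation). Of 13 interferon response genes 7 rose, 11 when adjusted over the list alone. The median was 2.19 (camera adjusted p = 1.52e-09; adjusted p = 0.314 with an estimated correlation). Each of those 7 calls was lost without at least 1 library. Isg15, a ubiquitin-like protein of the interferon response, rose to 122 ± 41.2 from 25.9 ± 12.7 CPM (2.23 ± 0.47, adjusted p = 0.0154). Its adjusted p was 0.0604 without saline replicate 4 and 0.0511 without PPE week 1 replicate 2, and the covariate ended its call as well (1.98). Chemokine and cytokine genes rose in 3 of 21 cases, 7 when adjusted over the list alone. Their median was 1.62 (camera adjusted p = 1.27e-07; adjusted p = 0.314 with an estimated correlation). T and NK cell genes rose in 3 of 13, 6 when adjusted over the list alone. The median was 2.04 (camera adjusted p = 2.86e-05; adjusted p = 0.347 with an estimated correlation). No gene was called by edgeR among 7 neutrophil genes, although 4 were higher at an unadjusted p under 0.05, 4 when adjusted over the list alone, 4 by DESeq2 and 0 by limma-voom. The median was 2.82 (camera adjusted p = 0.00258; adjusted p = 0.314 with an estimated correlation). The same held for 16 cell cycle genes, where edgeR called 0, also when adjusted over the list alone, with 4 higher at an unadjusted p under 0.05, 1 by DESeq2 and 3 by limma-voom. The median there was 0.69 (camera adjusted p = 0.000788; adjusted p = 0.424 with an estimated correlation). Dendritic cell and antigen presentation genes rose in 1 of 13, 6 when adjusted over the list alone. Here the median was 1.37 (camera adjusted p = 3.20e-05; adjusted p = 0.424 with an estimated correlation). Of 5 mast cell genes 1, Hdc, rose, also 1 when adjusted over the list alone, with a median of 0.03 (camera adjusted p = 0.412). None of 8 B and plasma cell genes was called by edgeR, DESeq2 or limma-voom, with 0 at an unadjusted p under 0.05 and a median of 0.89 (camera adjusted p = 0.431). Among genes always named, Adgre1, the macrophage surface protein F4/80, had a log2 fold change of 0.89 ± 0.34 (adjusted p = 0.146). That of the monocyte chemokine Ccl2 was 1.62 ± 0.70 (adjusted p = 0.203) and that of the cytokine Il1b 2.93 ± 0.91 (adjusted p = 0.0871).

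Genes of the matrix and of its breakdown passed the test in both directions at PPE week 1. Of 16 basement membrane genes 2 rose and 4 fell, 2 and 5 when adjusted over the list alone. Their median was -0.13 (camera adjusted p = 0.153). Of 21 matrix-degrading protease genes 2 rose and 2 fell, the same numbers when adjusted over the list alone. The list's median was 0.23 (camera adjusted p = 0.996). Mmp9, a gelatinase, was at 59.8 ± 27.5 against 16.1 ± 6.86 CPM without passing the test (1.89 ± 0.84, adjusted p = 0.225). The protease inhibitor list was lower, with 3 of 11 genes fallen, 5 lower and 1 higher when adjusted over the list alone. Their median was -0.32 (camera adjusted p = 0.0219; adjusted p = 0.314 with an estimated correlation). The camera adjusted p was 0.0580 without saline replicate 3, and the list was not called with scaling by library size only. A shift of like size was found in the reference genes list, which was higher, with 2 of 14 genes risen, 5 when adjusted over the list alone. The median of the reference genes was 0.34 (camera adjusted p = 0.0219, and 0.0508 without PPE week 1 replicate 2). With an estimated correlation their adjusted p was 0.314. Timp2, an inhibitor of matrix metalloproteinases, was 1.57-fold lower (-0.65 ± 0.13, adjusted p = 0.00634), a call that scaling by library size only (-0.37) and the covariate (-0.70) ended. Of 19 elastic fibre genes 2 rose and 1 fell, 5 and 4 when adjusted over the list alone. The median was 0.01 (camera adjusted p = 0.785). Eln, elastin itself, was at 4035 ± 755 against 6186 ± 1852 CPM (-0.62 ± 0.35, adjusted p = 0.353; NM_007925, chromosome 5, 134702595 to 134747368). The collagens Col1a1 (0.40 ± 0.14, adjusted p = 0.0951) and Col3a1 (0.13 ± 0.13, adjusted p = 0.652) did not pass the test. Ccn2, a matrix-associated growth factor, was 3.19-fold lower, at 329 ± 39.6 against 1049 ± 329 CPM (-1.67 ± 0.28, adjusted p = 0.00552), a call that the NR_046233 covariate ended (-1.90).

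At PPE week 1, 508 features were higher and 499 lower than in saline, 7.89% of those tested, and 331 and 258 of them by at least 2-fold. The 4 libraries of PPE week 1 lay wholly above or below those of saline in 21.1% of features, against 2.86% by chance. The fatty acid oxidation list was called lower, with 0 of 16 genes called and a median of -0.56 (camera adjusted p = 0.0243). Its camera adjusted p was 0.158, 0.118 and 0.0542 without saline replicate 1, saline replicate 4 and PPE week 1 replicate 4. White adipocyte genes had a median of -0.89 (camera adjusted p = 0.0515), with 0 of 11 called. Camera called this list lower without saline replicate 3 or 4, PPE week 1 replicate 1 or 3, or PPE week 2 replicate 1, 2 or 3. Its camera adjusted p was 0.00477 to 0.280 over all leave-outs. It was 0.00580 with scaling by library size only (-0.66), 0.0105 with the replicate block (-0.98) and 0.0353 with halved counts (-0.90). Neither list was called with an estimated correlation. A fit of only the 8 libraries called 1113 higher and 913 lower. Scaling by library size only, which moved the median of all features by 0.28, called 1034 higher and 195 lower. The higher count moved by over 1.5 times without saline replicate 2 (309), 3 (261) or 4 (210), PPE week 1 replicate 1 (259), 2 (156), 3 (278) or 4 (280) or PPE week 2 replicate 1 (789). The lower count did so without saline replicate 3 (315) or 4 (262) or PPE week 1 replicate 1 (277), 2 (222), 3 (306) or 4 (322).

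**Figure D1:**
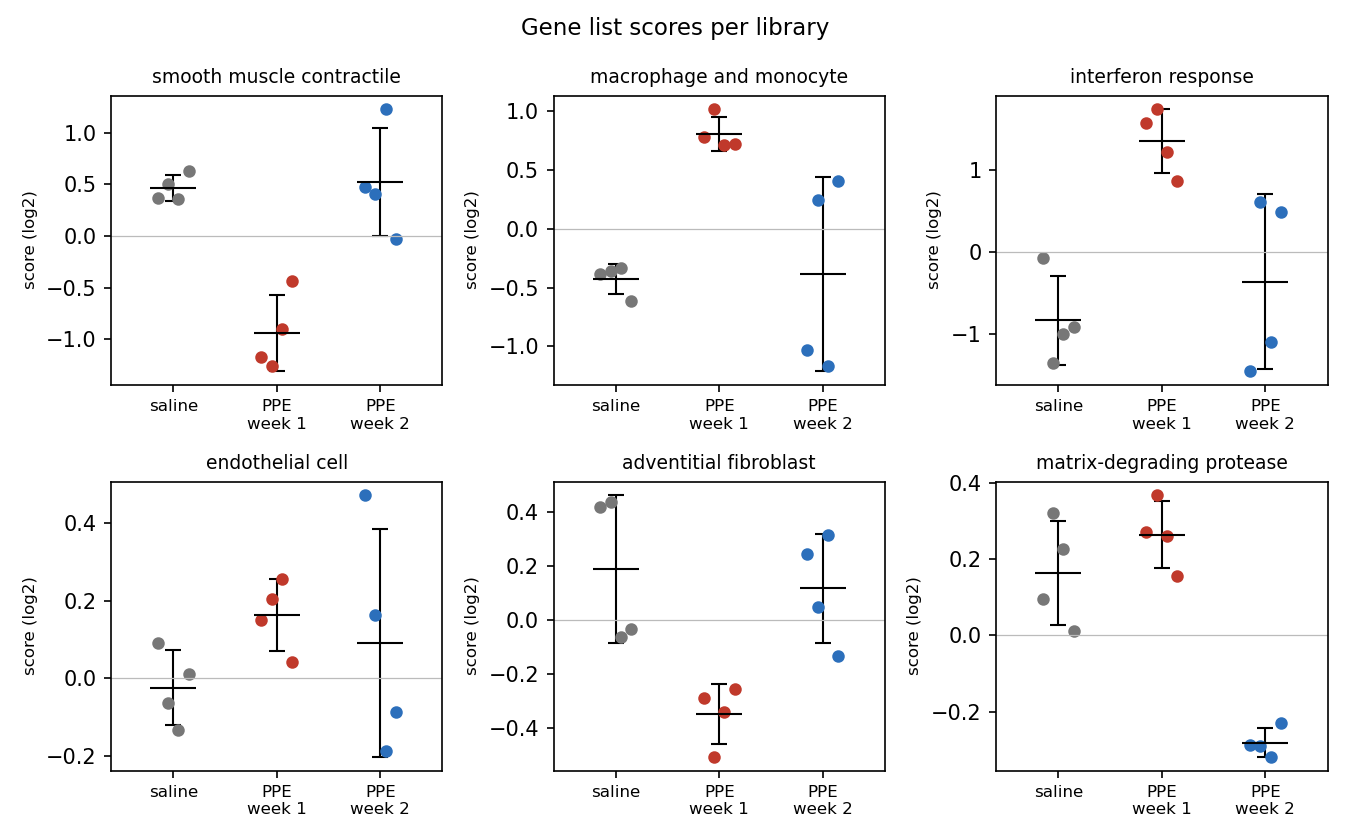
Score of 6 gene lists in each library (y axis, log2, the median over a list's genes relative to each gene's mean over the 12 libraries) by group; points are libraries, horizontal bars group means and error bars 1 SD (n = 4). The smooth muscle contractile score was 0.36 to 0.63 in saline and -1.26 to -0.43 at PPE week 1, and the macrophage and monocyte score was -1.17 to 0.41 at PPE week 2.

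The comparison of PPE week 2 with saline asks what differs 14 days after elastase, with a control taken at day 7, so that time after surgery differs as well. Some genes of the basement membrane were higher. Hspg2, which encodes perlecan, was at 3117 ± 641 CPM against 1735 ± 114 in saline (n = 4 each), 1.80-fold higher (0.85 ± 0.12, adjusted p = 0.00360; NM_008305, chromosome 4, 137468751 to 137570630). The basement membrane collagen Col18a1 was 3.02-fold higher (1.60 ± 0.30), and the proteoglycan Agrn 1.56-fold higher (0.64 ± 0.11). Some genes that break down matrix were lower. The stromelysin Mmp3 was 2.48-fold lower, at 99.1 ± 33.3 against 246 ± 32.8 CPM (-1.31 ± 0.22, adjusted p = 0.00734; NM_010809, chromosome 9, 7445822 to 7455975). Mmp14, a metalloproteinase of the cell membrane, was 1.82-fold lower, at 345 ± 79.6 against 629.6 ± 98.7 CPM (-0.87 ± 0.16, adjusted p = 0.00913; NM_008608, chromosome 14, 54431598 to 54442456). Scaling by library size only ended the call of Mmp14 (-0.36). Of 21 protease genes 4 fell and none rose, 5 when adjusted over the list alone. The list's median was -0.52 (camera adjusted p = 6.82e-07; adjusted p = 0.0555 with an estimated correlation; fry adjusted p = 0.00446). That median was 0.0191 with scaling by library size only, where the median of all features was 0.54. Of 16 basement membrane genes 6 rose, 7 when adjusted over the list alone, and 9 had a log2 fold change above 0. Their median was 0.20 (camera adjusted p = 0.0371; adjusted p = 0.982 with an estimated correlation). The list's call was lost without saline replicate 3 (adjusted p = 0.0606) or 4 (0.0588) or PPE week 2 replicate 1 (0.110) or 3 (0.181). The median was 0.01 to 0.33 over the 12 leave-outs. Of 14 activated fibroblast genes 3 fell, also 3 when adjusted over the list alone. For these genes the median was -0.53 (camera adjusted p = 0.000323; adjusted p = 0.310 with an estimated correlation). Among them was Cthrc1, a protein secreted by fibroblasts in injured arteries, at 11.5 ± 4.47 against 47.6 ± 13.9 CPM (-2.05 ± 0.30, adjusted p = 0.00360). Of 12 genes of endoplasmic reticulum stress and secretion 2 fell, 5 when adjusted over the list alone (median -0.46, and 0.0353 with scaling by library size only; camera adjusted p = 4.85e-05; adjusted p = 0.583 with an estimated correlation). These were the disulfide isomerase Pdia3, at 576 ± 55.8 against 889 ± 96.7 CPM (-0.63 ± 0.11), and the chaperone Hsp90b1 (-0.48 ± 0.11). With scaling by library size only neither was called (-0.12 and 0.0225), and the fit of only the 8 libraries and the replicate block did not call Hsp90b1 either. The adjusted p of Hsp90b1 was 0.0594 without saline replicate 2 and 0.0950 without saline replicate 3. The share of NR_046233 was lower in each of these PPE week 2 libraries than in each saline library.

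Most contractile and immune genes did not pass the test at PPE week 2, where their spread between libraries was wide. Acta2 was at 4418 ± 1750 against 3569 ± 512 CPM (0.31 ± 0.25, adjusted p = 0.602), and of the 19 contractile genes 1 rose, also 1 when adjusted over the list alone. Their median was 0.09 (camera adjusted p = 0.892). Without PPE week 2 replicate 3 it was -0.18 and the list was called lower (camera adjusted p = 0.0291, against 0.279 to 0.994 without any other library). The gene that rose was Tpm1, a tropomyosin (1.46 ± 0.31, adjusted p = 0.0209), which the fit of only the 8 libraries did not call. Its adjusted p was 0.0666 without saline replicate 1, 0.0763 without saline replicate 3 and 0.0552 without PPE week 2 replicate 3. Cd68 was at 51.1 ± 18.1 against 42.8 ± 4.90 CPM (0.25 ± 0.22, adjusted p = 0.636) and Cxcl10 at 26.7 ± 20.5 against 10.5 ± 5.89 CPM (1.33 ± 0.61, adjusted p = 0.305). None of 16 macrophage genes was called by edgeR, DESeq2 or limma-voom, with 0 higher and 1 lower at an unadjusted p under 0.05. None of 13 interferon response genes was called by these tools, with 1 higher at an unadjusted p under 0.05. As a list they were called higher by camera without saline replicate 1 (median 0.86, adjusted p = 0.0476) or PPE week 2 replicate 1 (0.74, adjusted p = 0.0183), against an adjusted p of 0.0559 to 0.961 without any other library. T and NK cell genes had a median of 1.51 (camera adjusted p = 0.300), with 12 of 13 above 0, 0 called by edgeR, also when adjusted over the list alone, 4 higher at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. That list was called higher without PPE week 2 replicate 1 (median 1.74, camera adjusted p = 0.0179, against 0.0507 to 0.770 without any other library). The replicate block also called it (1.02, camera adjusted p = 0.0408). So did the fit with saline replicate 2 and PPE week 2 replicate 1 both left out (1.90, camera adjusted p = 0.0374). B and plasma cell genes had a median of 1.91 (camera adjusted p = 0.120), with 0 of 8 called by edgeR, 3 higher when adjusted over the list alone, 4 higher at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom. That list was called higher without PPE week 2 replicate 3 (median 2.25, camera adjusted p = 0.0292, against 0.0762 to 0.251 without any other library). Dendritic cell and antigen presentation genes had a median of 0.67 (camera adjusted p = 0.606) and were called higher as a list without PPE week 2 replicate 3 (1.03, camera adjusted p = 0.0441, against 0.0644 to 0.951). In PPE week 2 replicates 1 to 4 the macrophage and monocyte score was -1.03, 0.25, -1.17 and 0.41, and the smooth muscle contractile score 0.48, 0.41, 1.23 and -0.03. Eln was at 8984 ± 4607 against 6186 ± 1852 CPM (0.54 ± 0.35, adjusted p = 0.499), and at 4088, 8377, 15214 and 8258 CPM in PPE week 2 replicates 1 to 4. Fbn1, fibrillin of the elastic microfibrils, fell to 1428 ± 172 from 2259 ± 219 CPM (-0.66 ± 0.11, adjusted p = 0.00420), a call that scaling by library size only ended (-0.16).

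Of 12 Schwann cell and neuron genes 1 rose at PPE week 2, 5 when adjusted over the list alone. The median was 1.96 (camera adjusted p = 0.00396; adjusted p = 0.982 with an estimated correlation). With scaling by library size only the list was not called (2.47). The gene was Th, tyrosine hydroxylase of sympathetic neurons, at 25.7 ± 22.5 against 0.605 ± 0.722 CPM (5.43 ± 1.24, adjusted p = 0.0439), and at 57.9, 24.0, 12.26 and 8.49 CPM in PPE week 2 replicates 1 to 4. Its adjusted p was 0.0530 to 0.131 without any of saline replicates 1 to 4, PPE week 1 replicates 2 and 3 or PPE week 2 replicates 2 and 4, and limma-voom, the fit without a low-count filter and the replicate block did not call it. Hmga2, a chromatin protein of growing cells, was 10.4-fold lower (-3.38 ± 0.59, adjusted p = 0.00734), a call that limma-voom did not make.

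At PPE week 2, 166 features were higher and 172 lower than in saline, 90 and 51 of them by at least 2-fold. The libraries did not overlap in 8.99% of features, against 2.86% by chance. A fit of only the 8 libraries called 33 higher and 41 lower, and limma-voom 78 and 85. The fit of all 12 libraries takes part of its spread from PPE week 1. There the median SD of log2 CPM between libraries was 0.349, against 0.504 in saline and 0.586 at PPE week 2. Scaling by library size only, which moved the median of all features by 0.49, called 1611 and 27. With the share of NR_046233 as a covariate edgeR called 0, with 588 at an unadjusted p under 0.05; DESeq2 without the covariate called 420 higher and 347 lower. The higher count was 87, 108, 67 and 74 without saline replicates 1 to 4 in turn, 110, 100 and 103 without PPE week 1 replicates 2 to 4, and 109 and 97 without PPE week 2 replicates 2 and 4. The lower count was 107, 98, 72 and 90 without saline replicates 1 to 4, 112 without PPE week 1 replicate 3, and 112 and 113 without PPE week 2 replicates 2 and 4.

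**Figure D2:**
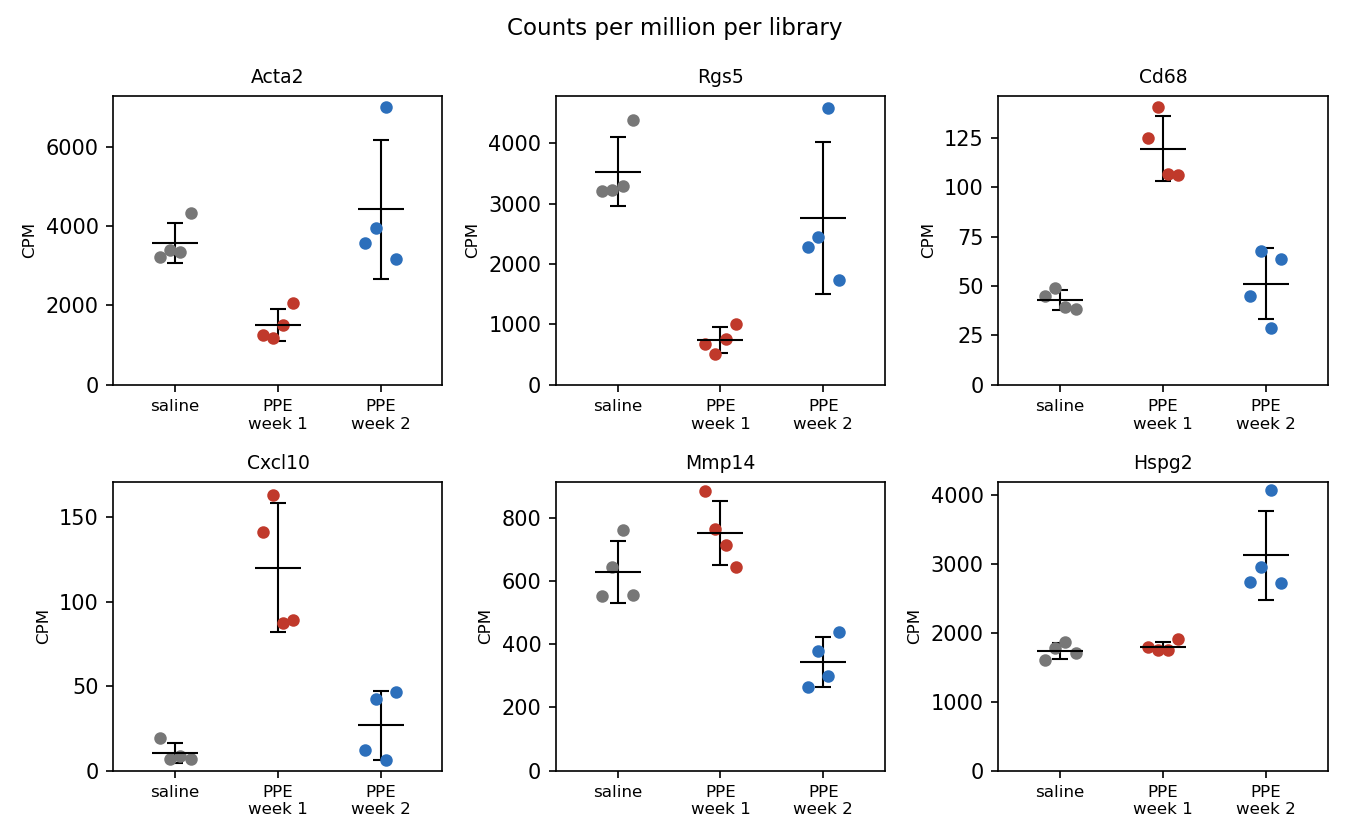
CPM (y axis, from 0) of Acta2, Rgs5, Cd68, Cxcl10, Mmp14 and Hspg2 in each library by group; points are libraries, horizontal bars group means and error bars 1 SD (n = 4). Cd68 had a mean of 42.8 in saline, 119.7 at PPE week 1 and 51.1 at PPE week 2, and Hspg2 of 1735, 1796 and 3117.

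The comparison of PPE week 2 with PPE week 1 tests the difference between the days after elastase directly, while the controls add only to the estimate of the spread. Contractile genes were higher at week 2. Acta2 was 2.95-fold higher (1.56 ± 0.25, adjusted p = 0.00431) and Cnn1 3.91-fold higher, at 258 ± 110 against 66.0 ± 23.0 CPM (1.97 ± 0.31, n = 4 each). Itga8 was 4.36-fold higher (2.12 ± 0.31) and Rgs5 3.76-fold higher (1.91 ± 0.30). Of 19 contractile genes 12 rose and none fell, 14 when adjusted over the list alone. The list's median was 1.56 (camera adjusted p = 4.99e-15; adjusted p = 0.230 with an estimated correlation; fry adjusted p = 0.0161). Laminins and perlecan of the basement membrane were higher as well. Lamb2 was 2.55-fold higher, at 618 ± 186 against 243 ± 52.0 CPM (1.35 ± 0.19), and Lama5 2.26-fold higher (1.18 ± 0.16, adjusted p = 0.00104). Of 16 basement membrane genes 6 rose and 1 fell, 8 and 1 when adjusted over the list alone. The median was 0.63 (camera adjusted p = 7.36e-05; adjusted p = 0.265 with an estimated correlation). Sost, the secreted Wnt inhibitor sclerostin, was 16.3-fold higher, at 285 ± 241 against 17.6 ± 11.8 CPM (4.02 ± 0.61, adjusted p = 0.00490). It had 646 CPM in PPE week 2 replicate 3 and 152 to 184 in the others. Cd68 was 2.34-fold lower at week 2 (-1.23 ± 0.22, adjusted p = 0.00403). Of 16 macrophage genes 3 fell, 6 when adjusted over the list alone. The list's median was -0.93 (camera adjusted p = 9.71e-09; adjusted p = 0.230 with an estimated correlation). Of 13 interferon response genes 1 fell, 8 when adjusted over the list alone. Their median was -1.43 (camera adjusted p = 5.72e-08; adjusted p = 0.230 with an estimated correlation). The gene that fell was Isg15 (-2.15 ± 0.47, adjusted p = 0.0194). The adjusted p of Isg15 was 0.0559 without PPE week 1 replicate 1, 0.0663 without PPE week 1 replicate 2 and 0.0696 without PPE week 2 replicate 3, and the fit without a low-count filter did not call it. Of 21 protease genes 3 fell, 8 when adjusted over the list alone. The median was -0.48 (camera adjusted p = 1.13e-05; adjusted p = 0.154 with an estimated correlation). Among them was Mmp14, 2.18-fold lower (-1.12 ± 0.16, adjusted p = 0.00109). Has2, which makes hyaluronan, was 8.82-fold lower, at 3.01 ± 2.30 against 26.5 ± 5.78 CPM (-3.14 ± 0.53), and Adam12, a metalloproteinase of activated fibroblasts, 3.61-fold lower (-1.85 ± 0.22). Of 16 cell cycle genes 3 fell, 9 when adjusted over the list alone. Cell cycle genes had a median of -1.005 (camera adjusted p = 3.42e-06; adjusted p = 0.230 with an estimated correlation). Mki67, a marker of dividing cells, was at 121 ± 61.0 against 278 ± 12.6 CPM (-1.20 ± 0.29, adjusted p = 0.0277). Its adjusted p was 0.0680, 0.0848, 0.0655 and 0.0544 without PPE week 1 replicates 1 to 4 in turn and 0.0896 without PPE week 2 replicate 3. Scaling by library size only, the fit without a low-count filter and that of only the 8 libraries did not call Mki67.

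Between the PPE weeks 481 features were higher and 360 lower at week 2, 309 and 168 by at least 2-fold. The libraries did not overlap in 15.9% of features, against 2.86% by chance. Of the features lower at week 1 than in saline 271 were higher at week 2 than at week 1, against 18.8 if the calls were independent. Of those higher at week 1, 120 were lower at week 2, against 14.3. Both pairs of comparisons share the PPE week 1 libraries, which by itself makes such overlaps larger. The share of NR_046233 was 20.4% ± 1.13 at week 2 and 30.4% ± 6.34 at week 1 (SD, n = 4). With it as a covariate edgeR called 0, with 1356 at an unadjusted p under 0.05, while DESeq2 and limma-voom without it called 1493 and 955. A fit of only the 8 libraries called 337 higher and 184 lower. The higher count was 242, 207, 295 and 315 without PPE week 1 replicates 1 to 4 and 222 without PPE week 2 replicate 3. The lower count was 145, 112, 202 and 188 without PPE week 1 replicates 1 to 4 and 233, 160 and 607 without PPE week 2 replicates 1, 3 and 4.

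The differences of both PPE weeks from saline correlated across features with a Pearson r of 0.588. Groups simulated without a change, with 4 controls drawn anew and shared by both differences, gave 0.508 ± 0.0129 (SD, 20 simulations). Both differences had the same sign in 66.8% of features, against 66.9% ± 0.352 in the simulations. With the controls split into 2 and 2, so that no control served both and each difference rested on 2 of them, r was 0.185 to 0.228 over the 6 splits. Of the features called, 74 were higher in both weeks, against 6.61 if independent and 0.1 on average in the simulations. A further 41 were lower in both, against 6.73 and 0. None was higher at week 1 and lower at week 2 among edgeR's calls, and 1 was lower at week 1 and higher at week 2. The simulations held no changed gene, so an overlap near 0 was set in advance there. The overlap if independent leaves out the shared controls. With the controls split, 0 to 4 features were higher in both weeks and 0 to 5 lower in both. Fewer features were called in those splits, 171 to 432 at week 1 and 18 to 112 at week 2.

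The authors' deposited comparison tables list 13810 accessions for week 1, of which 1274 were higher and 1129 lower at an adjusted p under 0.05. They list 9917 for week 2, of which 218 were higher and 162 lower. The direction of their log2 fold changes, which the tables do not state, was PPE minus saline by recomputation. Their log2 fold changes and the recomputed ones had the same sign in 98.7% of accessions for week 1 (r = 0.920 across accessions) and 99.6% for week 2 (r = 0.932). Of the 1007 features called here for week 1 their table calls 1006, and of the 338 for week 2 it calls 291.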

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

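The tests of a lower share of smooth muscle cells, of dilution by leukocytes, of a difference in depth, of other ways to split the libraries, of the scores of PPE week 2 replicates 2 to 4, of halved counts, of saline replicate 2 and PPE week 2 replicate 1 both left out, and of the NR_046233 share as a covariate were chosen only after the result was seen; the other tests below were written down before the result each one measures.

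Other ways of splitting 8 libraries into 4 and 4 were counted for each comparison, and they argue against chance in all 3. In each, 1 of the 35 splits, the real one, called as many genes, the smallest share that 35 splits allow. Every other split mixes the 2 groups, so that a real difference adds to its spread and lowers its calls. PPE week 1 against saline called 1007 in the real split and at most 1 in any other. PPE week 2 against saline called 338 and at most 26, and PPE week 2 against PPE week 1 called 841 and 0. EdgeR was fitted each time to all 12 libraries, and the third group kept its labels. In the last comparison the other splits gave up to 1334 features at an unadjusted p under 0.05, and DESeq2 and limma-voom were not run on other splits.

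Smooth muscle contractile genes were lower at PPE week 1 than in saline; a lower share of smooth muscle cells alone would raise the markers of every other cell type alike, but the mean macrophage score minus the mean adventitial fibroblast score changed by 1.61 (exact permutation p = 0.0286; 1.77 with medians over genes). Dilution of all resident cells by leukocytes alone would lower endothelial genes as much, but the mean endothelial score minus the mean contractile score changed by 1.54 (exact permutation p = 0.0286; 1.59 with medians). Carry-over of ribosomal RNA is argued against by the slope of the mean contractile score on the log2 share of NR_046233 within groups, which gives a change of -0.00892 (95% interval -0.61 to 0.60) where -1.40 was observed, and gene length and GC content are argued against as well, since the list's median set against genes of like length and GC content was -1.27 (95% interval -1.89 to -0.87), beside -1.25 as measured. With the share of NR_046233 as a covariate 3 of 19 genes were called where 13 were, with a median of -1.28 and a median standard error of 0.416 in place of 0.305. The list's median thus kept its size while the error grew. Of single genes, Acta2 then changed by slightly more, and Cnn1 and Myh11 by less. What ended each call was not tested. Lower expression within smooth muscle cells, and several changes in cell share at once, may each contribute and stay open.

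When only the total count scales the libraries, the median log2 fold change of all genes at PPE week 2 was 0.54, where it was 0.05 with TMM. A difference in depth is argued against by the ratio of the mean total counts of PPE week 2 and saline, 0.992 (exact permutation p = 0.943). A smaller share of counts for NR_046233 is consistent with the shift, since total counts without that accession gave a median of 0.101. Why the share of NR_046233 was smaller after PPE was not tested, and both the preparation of the RNA and the tissue stay open.

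Schwann cell and neuron genes were higher at PPE week 2 than in saline, by a median of 1.96 (log2). Nerve tissue carried along with some samples is consistent with the levels of 16 tested sympathetic neuron markers, fixed before the test, of which 6 are also in the list: their median pairwise correlation within groups was 0.712, and that of random sets of genes lay between -0.0792 and 0.0986. Among the most abundant, Dbh was at 213.7, 46.5, 18.7 and 31.4 CPM in PPE week 2 replicates 1 to 4 and at 0.918, 10.9, 48.1 and 77.3 CPM in PPE week 1 replicates 1 to 4. Whether PPE week 2 replicate 1 was the only source was not decided, since both tests missed the thresholds set for arguing against it. Without it the median was 1.38, a smaller share of 1.96 than the rule set beforehand asked for. The list kept its camera call, which that rule did not use (camera adjusted p = 0.0183, and 0.000384 to 0.0159 without any other library). The scores of the other 3 libraries, 0.77 to 0.94, all lay above those of saline, -1.68 to 0.33 (difference 1.73, exact permutation p = 0.0571). The part of PPE week 2 replicate 1 in the rise stays open. A change in the innervation of the aorta after PPE, the biological explanation the design gives, may also hold and was not tested. The markers would also rise and fall together if innervation differed between animals. Their correlation therefore does not tell such a change from nerve tissue carried along.

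Of 498 groups of 4 libraries tested for a value far from the others, 20 had one, where chance gives about 1 in 20 groups, or 24.9. In saline, Itga8 was at 1643 CPM in saline replicate 4 and 1246 to 1287 in the others. Rgs5 was at 4396 in saline replicate 4 and 3212 to 3286 in the others, and Synpo2 was at 201 in saline replicate 3 and 297 to 318 in the others. Adgre1 was at 179 CPM in saline replicate 2 and 136 to 141 in the others, and Hspa1a at 17.0 in saline replicate 1 and 43.4 to 46.2 in the others. At PPE week 1, replicate 2 stood apart in Pi16, at 99.2 CPM against 78.3 to 80.8, and in H2-DMa, at 99.4 against 75.3 to 76.4. It also did in Ctsl, at 358 against 391.8 to 398, and in B2m, at 3061 against 2264 to 2370. Also at PPE week 1, the mean TGF-beta signalling and response score was 0.18 in replicate 1 and -0.07 to -0.04 in the others, which did not hold for the median over genes (-0.14 to 0.15 over the 4 libraries). Of the scores that are medians over genes, fibrillar collagen was at 0.35 in PPE week 1 replicate 1 and 0.0961 to 0.13 in the others, and lymphatic endothelial cell at 0.45 in that library and 0.0339 to 0.10 in the others. In PPE week 1 replicate 3 the skeletal muscle score was 1.36, with -0.20 to -0.12 in the others, and the score of immediate early genes -0.22, with 0.11 to 0.18. The cell cycle score was -0.49 in saline replicate 1 and -0.00836 to 0.0897 in the others. The Schwann cell and neuron score was 2.06 in PPE week 2 replicate 1 and 0.77 to 0.94 in the others. Col19a1 was at 0.374 CPM in PPE week 1 replicate 3 and 3.95 to 5.09 in the others of that group, and Hspa1a at 9.28 in PPE week 1 replicate 4 and 6.24 to 6.58 in the others. At PPE week 2, Sost was at 646 CPM in replicate 3 and 152 to 184 in the others, and Agtr1a at 3.45 in replicate 4 and 10.2 to 12.4 in the others.

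The direct test of PPE week 2 against PPE week 1 found a difference between the weeks in 481 features that were higher and 360 that were lower. Gene lists called higher at week 2 by camera had median log2 fold changes of 1.56 for smooth muscle contractile, 1.29 for smooth muscle ion channel and signalling, 0.81 for vascular smooth muscle transcription factor, 0.63 for basement membrane. They were 0.42 for adventitial fibroblast, 1.37 for white adipocyte, 2.62 for brown adipocyte, 0.81 for Schwann cell and neuron, 0.38 for oxidative phosphorylation and 0.84 for fatty acid oxidation. Lists called lower had medians of -0.31 for fibrillar collagen, -0.48 for matrix-degrading protease, -0.93 for macrophage and monocyte, -2.99 for neutrophil, -0.77 for T and NK cell, -0.64 for dendritic cell and antigen presentation. They were -1.29 for chemokine and cytokine, -1.43 for interferon response, -1.005 for cell cycle, -0.54 for activated fibroblast, -0.31 for ER stress and secretory, -0.46 for lipid handling of macrophages and -0.45 for reference genes. The T and NK cell score was -1.7, 1.345, -0.841 and 1.642 in PPE week 2 replicates 1 to 4, and 1.098 to 1.503 at PPE week 1. The dendritic cell and antigen presentation score was -1.183, 0.755, -1.27 and 0.966, and 0.713 to 0.869 at PPE week 1. In these lists only PPE week 2 replicates 1 and 3 lay below every PPE week 1 library. The adjusted p was 0.0636 for white adipocyte and 0.197 for oxidative phosphorylation without PPE week 2 replicate 1. It was 0.0526 for lipid handling without PPE week 2 replicate 3. It was 0.124 and 0.0538 for Schwann cell and neuron without PPE week 1 replicate 1 and PPE week 2 replicate 1, and 0.0797, 0.0547 and 0.0899 for reference genes without PPE week 1 replicate 2, PPE week 1 replicate 4 and PPE week 2 replicate 3. Scaling by library size only ended the calls of fibrillar collagen (-0.10) and reference genes (-0.23), and halved counts that of brown adipocyte (2.64). With saline replicate 2 and PPE week 2 replicate 1 both left out, white adipocyte (0.91), brown adipocyte (1.74), Schwann cell and neuron (0.12) and oxidative phosphorylation (0.11) were not called. No list was called with an estimated correlation, where 6 had an unadjusted p under 0.05 in camera. Among the genes always named, the difference was 1.56 for Acta2, 2.59 for Myh11, 1.97 for Cnn1, -1.23 for Cd68, -1.20 for Mki67 and -0.78 for Mmp3. The adjusted p of Mmp3 was 0.0441, and 0.0522 to 0.128 without any of saline replicates 1 to 4, PPE week 1 replicates 1, 2 and 4 or PPE week 2 replicates 1 and 3. Scaling by library size only (-0.54) and the fit of only the 8 libraries (-0.77) did not call Mmp3 either. The adjusted p of Mki67 was 0.0277, and 0.0544 to 0.0896 without any of PPE week 1 replicates 1 to 4 or PPE week 2 replicate 3.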

How the results depend on the processing

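The alternatives with NR_046233, Lars2 and Mir6236 left out, counts summed per gene, counts halved, saline replicate 2 and PPE week 2 replicate 1 both left out, and the NR_046233 share as a covariate were chosen only after the data were seen. Of the values for named genes under all alternatives, 11477 kept their side of the threshold, 1337 lost the call, 326 gained it and 2 reversed. Reversed means a change of sign where either fit made the call. The 11477 include 110 that changed sign without a call in either fit. Of the values for gene lists 2160 kept their side of the threshold, 70 lost the call, 42 gained it and 8 reversed. Changes of sign without a call are among the 2160 as well and were not counted. The cause was not tested unless given. Depth can limit the precision, which was not tested: 4835305 to 9169690 counts per library were left beside NR_046233.

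Counts are given as higher and lower, for PPE week 1 against saline, PPE week 2 against saline and PPE week 2 against PPE week 1. DESeq2 called 857 and 790, 420 and 347, and 830 and 663, among them 996 of 1007, 338 of 338 and 836 of 841 of the calls. Limma-voom called 1043 and 849, and 78 and 85, and kept within 1.5 times for the third. Library size only called 1034 and 195, 1611 and 27, and 682 and 75, since it moves the median of all genes by 0.28, 0.49 and 0.21; with it 84.1, 98.4 and 90.1% of calls were higher, where 50.4, 49.1 and 57.2% were. Only the 8 libraries compared called 1113 and 913, 33 and 41, and 337 and 184. The replicate block called 91 and 113 at week 2; replicate numbers showed no pairing. An adjusted p under 0.01 left 101 and 182, 25 and 38, and 182 and 72, and glmTreat against a fold of 1.5 left 30 and 71, 0 and 0, and 89 and 16, with 717 at an unadjusted p under 0.05 for week 2 in glmTreat. The NR_046233 covariate left 31 and 73, 0 and 0, and 0 and 0 by edgeR, with 1876, 588 and 1356 at an unadjusted p under 0.05; the share differs between the groups, and the median standard error of all genes rose from 0.408 to 0.562 at week 1. Leaving out 1 library gave 156 to 789 and 222 to 607 at week 1, 67 to 218 and 72 to 198 at week 2, and 207 to 642 and 112 to 607 between weeks. The libraries concerned are named beside each count in the results; both left out gave 631 and 508, 187 and 121, and 372 and 242.

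Gene lists called by camera numbered 9 higher and 6 lower, 2 and 3, and 10 and 13; with an estimated correlation they were 0 and 0 in each, with 4, 3 and 6 lists at an unadjusted p under 0.05. Leaving out 1 library gave 1 to 5 higher and 3 to 5 lower at week 2. Medians reversed with library size only for vascular smooth muscle transcription factors at week 1 (0.0484) and, at week 2 against saline, for matrix-degrading protease (0.0191), neutrophil (0.37), cell cycle (0.0143) and ER stress (0.0353), and so did Hsp90b1 (0.0225). The smooth muscle contractile list at week 2 was -0.18 to 0.24 over leave-outs, and it reversed and was called lower without PPE week 2 replicate 3 (camera adjusted p = 0.0291, against 0.279 to 0.994 without any other library). The TGF-beta list between weeks was -0.10 to 0.14 over leave-outs. It reversed to 0.0709 and was called without PPE week 2 replicate 1 (camera adjusted p = 0.0247). With both libraries left out it was 0.0719 and called as well (camera adjusted p = 0.0270). Lars2 at week 2 was 0.11 with the covariate.

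The r of the differences from saline, 0.588, was 0.208, 0.211, 0.199, 0.228, 0.185 and 0.201 with split controls, where no control is shared and each difference rests on 2 controls, 0.499 by limma-voom, 0.438 with at least 1 CPM per group, 0.491 with 8 libraries, 0.682 with both left out, 0.697 with the covariate and 0.464 to 0.699 over leave-outs. The r with the authors' table for week 1, 0.920, was 0.883 by DESeq2, 0.883 by limma-voom, 0.872 without a filter, 0.987 with at least 1 CPM, 0.964 with 8 libraries, 0.865 with the block, 0.957 with halved counts, 0.833 with both left out, 0.801 with the covariate and 0.825 to 0.904 over leave-outs. That for week 2, 0.932, was 0.844 by limma-voom, 0.905 with the block, 0.825 with both left out, 0.616 with the covariate and 0.864 to 0.932 over leave-outs.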

Other observations

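The genes and gene lists in this part, and the NR_046233 share as a covariate, were chosen after the values were seen. They are given as values only. The call of each gene named in this part was kept in each fit that left out 1 of the 12 libraries.

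Of 11 complement genes 3 were higher and 2 lower at PPE week 1 than in saline, the same numbers when adjusted over the list alone. Their median log2 fold change was 0.58 (camera adjusted p = 0.158). Cfp, which encodes properdin, was 3.20-fold higher at week 1 than in saline, at 114 ± 30.3 against 35.6 ± 6.12 CPM (mean ± SD, n = 4 each; log2 fold change 1.68 ± 0.27 SE, adjusted p = 0.00213).

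Of 16 genes of the immediate early response and of stress at dissection 3 were higher and 2 lower at PPE week 1, 5 and 3 when adjusted over the list alone. The median of that list was 0.17 (camera adjusted p = 0.269). Fos, a transcription factor of that response, was 2.94-fold higher, at 69.7 ± 24.2 against 23.7 ± 8.61 CPM (1.56 ± 0.29, adjusted p = 0.00407).

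Of 9 brown adipocyte genes 1 was lower at PPE week 1 than in saline, 4 when adjusted over the list alone. The median of that list was -2.17 (camera adjusted p = 0.00376; adjusted p = 0.442 with an estimated correlation). The gene was Dio2, a deiodinase that activates thyroid hormone, at 7.33 ± 3.02 against 39.3 ± 11.99 CPM (-2.43 ± 0.43, adjusted p = 0.00361). Its call ended with the NR_046233 share as a covariate (-2.08). Over the 12 fits that left out 1 library the list's median was -2.32 to -1.75. Of 11 genes of lipid handling of macrophages 2 were higher at PPE week 1, 3 when adjusted over the list alone. There the median was 0.30 (camera adjusted p = 0.0113; adjusted p = 0.314 with an estimated correlation). Npc2, a lysosomal cholesterol carrier, was 1.88-fold higher, at 344 ± 35.2 against 183 ± 20.2 CPM (0.91 ± 0.17, adjusted p = 0.00520). Its call ended with the same covariate (0.83).

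Of 19 elastic fibre genes 2 were higher and 5 lower at PPE week 2 than at PPE week 1, 4 and 5 when adjusted over the list alone. The median over all of them was -0.08 (camera adjusted p = 0.598). Ltbp3, a binding protein of latent TGF-beta, was 1.91-fold higher, at 391 ± 50.7 against 205 ± 17.5 CPM (0.93 ± 0.13, adjusted p = 0.00109), and its call ended with the same covariate (0.92).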
